A study of Malus domestica with 6 samples.

How the data were processed

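Gene expression was measured by RNA sequencing in the skin of mature apple fruit (Malus domestica, cultivar 'Royal Gala') from wild-type (WT) plants and from plants carrying a miR172 transgene, with 3 libraries per genotype. Per the labels' protocols, strand-specific libraries were made from poly-A RNA, sequenced as paired-end reads and aligned to the GDDH13 apple genome with Bowtie2. The submitters' processing notes list other tools without their roles: HISAT2 version 2.0.5, StringTie version 1.3.3b, featureCounts version 1.5.0-p3 and DESeq2 version 1.16.1. Which aligner produced the deposited values, the annotation release and the strand setting of the counting are not given in the sources used here. The labels call the libraries biological samples but do not say whether they came from separate plants or fruit, so p-values measure the spread between these libraries, which may in part be technical. The sample titles name no transgenic line. If all miR172 libraries came from a single line, an effect of that line could not be told apart from one of miR172.

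The deposited values are FPKM (fragments per kilobase of gene, scaled to library size), per the file headers, with 1 column per library and 48602 rows. Of these rows, 46558 carry identifiers that begin with MD, and 2044 are loci with no MD identifier, which took between 0.322% and 0.544% of each library's recovered reads and were kept in the tests. MD identifiers are printed without the prefix that the files put before them. Another 12 columns of per-sample values, in 4 tables, were not used here, because no sample described in the labels held here matches them.

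The files do not pair identifiers with gene names. The gene table at hand belongs to another apple assembly, GDT2T_hap1, and 0 of the 48602 identifiers matched an entry in it, so no gene is named here. Tests of gene lists, including AP2-like factors and the flavonoid pathway to anthocyanin, a search for miR172 sites in transcripts and a check of the miR172 precursor had been laid down, and none could be run without names or sequences. Coordinates were not used here, and reads shared between near-identical gene copies or overlapping genes could not be looked for in sequence, so values of single genes carry that uncertainty.

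Whole reads were recovered from the deposited FPKM. Within a gene, values of different libraries stand in ratios of whole numbers times a constant for each pair of libraries, which gave each library's divisor. For each gene, lengths between 50 and 40000 bases were then searched for the shortest that made the reads of all libraries whole, within 0.0001 reads plus a relative tolerance of 3e-09. Reads came out whole for all 37804 genes above 0 in some library, and the other 10798 rows, at 0 in all libraries, test nothing. The result is best constrained for the 23856 genes above 0 in all 6 libraries, and for genes seen in few libraries a shorter length with fewer reads can pass. In simulated data with 6000 genes, reads were returned exactly for 99.1% of the 5694 genes present in all libraries, and 0.0527% of those genes came out whole when the divisors of some libraries were deliberately wrong. The divisors behind the authors' FPKM were 0.883, 0.833 and 0.855 times the recovered read total in WT replicates 1, 2 and 3, and 1.20, 1.08 and 0.899 times the total in miR172 replicates 1, 2 and 3. The FPKM thus carry a scaling between libraries whose method is not given in the sources used here, and it bears on how many genes count as higher or lower.

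The test, its filter, pseudocount and threshold, the rule for named genes and the first group of alternatives below were fixed before the data were examined. The test was limma version 3.58.1 in R version 4.3.3, with a mean-variance trend and robust empirical Bayes, on log2(FPKM + 1), for the 24668 genes with a mean of at least 1 FPKM over the 6 libraries. It was two-sided with Benjamini-Hochberg adjustment and a threshold of adjusted p = 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. With no names to pair, the rule named the 2 identifiers with the largest rise and the 2 with the largest fall past the threshold. Data for WT against miR172 skin were simulated from the real means and observed spreads of the 22445 tested genes above 0 in all 6 libraries. The observed spreads already hold counting noise, which the simulation added again. In the simulated data limma called 0% of 100 genes changed 2-fold, 33% of 100 genes changed 4-fold, and 1 unchanged gene. Far fewer genes were changed in the simulation than the 2118 called in the real data, which makes the adjustment stricter there. Those shares may thus understate what the real test could call. Of the 2118 called genes 2041 changed at least 2-fold, so some smaller changes did pass. A gene that did not pass may still have changed by several fold.

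The alternatives fixed at that stage were median-ratio scaling, no filter, a filter of 5 FPKM, pseudocounts of 0.1 and 5, the replicate number as a block, each library left out in turn, no mean-variance trend, and an added requirement of a 2-fold change. Scaling to recovered read totals, limma's voom on recovered reads and reads thinned to the smallest total were chosen after seeing the data. So were the description of direction by level, with its class limits of 1, 10, 100 and 1000 FPKM, the tabulation by identifier code and of loci with no MD identifier, and the principal components. Read recovery used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Intervals of shares are exact Clopper-Pearson intervals at 95% that treat genes as independent, which they are not. The floor of 3 reads covers counting error only.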

Results

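The study's title links miR172, a microRNA that represses APETALA2-type transcription factors in plants, to the synthesis of anthocyanins, the pigments behind red apple skin. The comparison here asks which genes differ in level between the mature fruit skin of miR172 transgenic and WT 'Royal Gala', with 3 libraries per genotype. Recovered reads totalled 18954901, 17012710 and 23702606 in WT replicates 1, 2 and 3, and 19364007, 22809888 and 18761797 in miR172 replicates 1, 2 and 3. The number of genes at 1 FPKM or more was 23305, 22458 and 22715 in the WT replicates and 25536, 24992 and 23639 in the miR172 replicates. The files do not pair identifiers with gene names, so levels of miR172 targets and of pigment genes are not given.

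Fruit skin of the 2 genotypes differed at 2118 of 24668 genes tested, of which 1291 were higher and 827 lower in miR172 skin (limma, adjusted p = 0.05). The median log2 fold change was 2.05 among genes that rose and -1.60 among genes that fell, and 2041 of the 2118 changed at least 2-fold. Changes of at least 4-fold were found in 678 genes that rose and 256 that fell, and changes of at least 16-fold in 92 and 34 genes. In all 2118 genes the 3 libraries of each genotype did not overlap. Selection by a small p-value makes this likely, so it adds no support for these genes. Of all tested genes 30.1% did not overlap, where chance gives 10% per gene. Genes of the same 6 libraries vary together, so the 2 shares were not compared by a test.

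The balance of directions moved with scaling to recovered read totals and with the level of the genes tested, but little with median-ratio scaling. Under median-ratio scaling 1325 genes were higher and 786 lower, or 62.8% higher. Scaling to recovered read totals moved the median log2 fold change of all tested genes from -0.0033 to 0.26, and 1681 genes were then higher and 471 lower, or 78.1% higher against 61.0%. With a filter of 5 FPKM 732 of 1480 called genes were higher, with no filter 534 of 1622 were lower, and voom on recovered reads called 1268 genes, 631 of them higher. Single libraries also moved the counts. Without WT replicate 2, 788 genes were higher and 357 lower, and without WT replicate 3 these numbers were 672 and 248. Without miR172 replicate 1 they were 534 and 282, and without miR172 replicate 2 they were 564 and 269. A set of 657 genes, 459 higher and 198 lower, passed the threshold in the full data and with each of the 6 libraries left out. In these fits 0 of the 2118 genes changed sign. Where genotypes do not overlap, leaving out a library cannot reverse the sign, so this adds no support.

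The identifier with the largest rise on the log2(FPKM + 1) scale was MD01G1175700. It had 0 recovered reads in all 3 WT libraries and 2723, 4684 and 3325 in miR172 replicates 1, 2 and 3, where it stood at 104 ± 27.4 FPKM (SD, n = 3). Its log2 fold change was 6.68 ± 0.26 (SE, limma adjusted p = 0.00011). Against a floor of 3 reads over the WT group, it was at least 2863-fold higher in miR172 skin, or at least 1729-fold without WT replicate 3, where fewer reads stand behind the floor. MD10G1160400 rose from 0.139 ± 0.132 to 176 ± 179 FPKM (SD, n = 3), with a log2 fold change of 6.62 ± 0.78 (SE, limma adjusted p = 0.0025). Its miR172 replicates were uneven, at 125, 28.4 and 375 FPKM, and its WT replicates held 4, 2 and 0 recovered reads. With voom on recovered reads its adjusted p was 0.21, against 0.0019 to 0.017 in the other alternatives.

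The identifier with the largest fall was MD08G1062400, at 176 ± 53.9 FPKM in WT and 0.290 ± 0.416 FPKM in miR172 skin (SD, n = 3). It had 1606, 1083 and 1026 recovered reads in the WT replicates and 1, 8 and 0 in the miR172 replicates. Its log2 fold change was -7.10 ± 0.33 (SE, limma adjusted p = 0.00012). MD10G1101200 was more abundant and fell from 396 ± 48.9 to 5.72 ± 5.16 FPKM (SD, n = 3), which is 69.3-fold lower by group means. The fall was 123-fold without miR172 replicate 2 and 47.3-fold without miR172 replicate 3. The log2 fold change of MD10G1101200 was -6.34 ± 0.68 (SE, limma adjusted p = 0.0017), with 197, 374 and 10 recovered reads left in the miR172 replicates. MD01G1175700, MD08G1062400 and MD10G1101200 passed the threshold in all alternatives run.

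**Figure D1:**
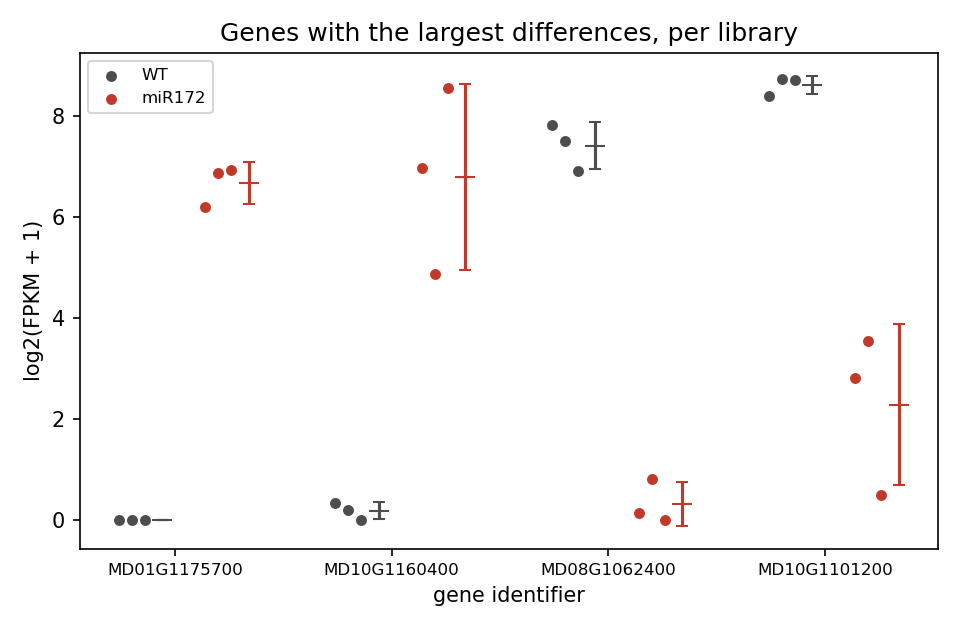
Level in log2(FPKM + 1) of the 2 identifiers with the largest rise and the 2 with the largest fall in miR172 fruit skin, with 1 point per library (3 per genotype, WT in grey and miR172 in red) and the mean ± SD of the log2 values beside the points. MD01G1175700 lies at 0 in all WT libraries, and the miR172 points of MD10G1160400 and MD10G1101200 are the most scattered.

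Direction differed with expression level. The miR172 libraries, which held more genes at 1 FPKM or more, also did so after scaling to recovered totals, with 26625, 25527 and 23418 genes against 22989, 21979 and 22314 in WT. Among genes with a mean of 1 to 10 FPKM 828 rose and 206 fell, and at 10 to 100 FPKM 439 rose and 503 fell. At 100 to 1000 FPKM 23 rose and 108 fell, and of the 52 genes tested at 1000 FPKM or more, 1 rose and 10 fell. Of the 142 changed genes with at least 100 FPKM, 118 were lower in miR172 skin, or 83.1% (95% interval 75.9 to 88.9%). The split of directions differed from that of the less abundant changed genes (two-sided Fisher's exact test across genes, which are not independent replicates, p = 1.35e-28). With median-ratio scaling the share lower was 82.0% of 139 genes. It was 66.4% of 131 genes when values were scaled to recovered totals, 64.5% of 62 genes without WT replicate 2, and 63.5% of 52 genes without WT replicate 3. In the last case the 95% interval, 49.0 to 76.4%, included equal numbers. Without miR172 replicate 3 the share was 89.9%, or 214 of 238 genes. It was 80.3% without miR172 replicate 1 (53 of 66 genes), 81.0% without miR172 replicate 2 (47 of 58 genes) and 79.8% without WT replicate 1 (154 of 193 genes).

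**Figure D2:**
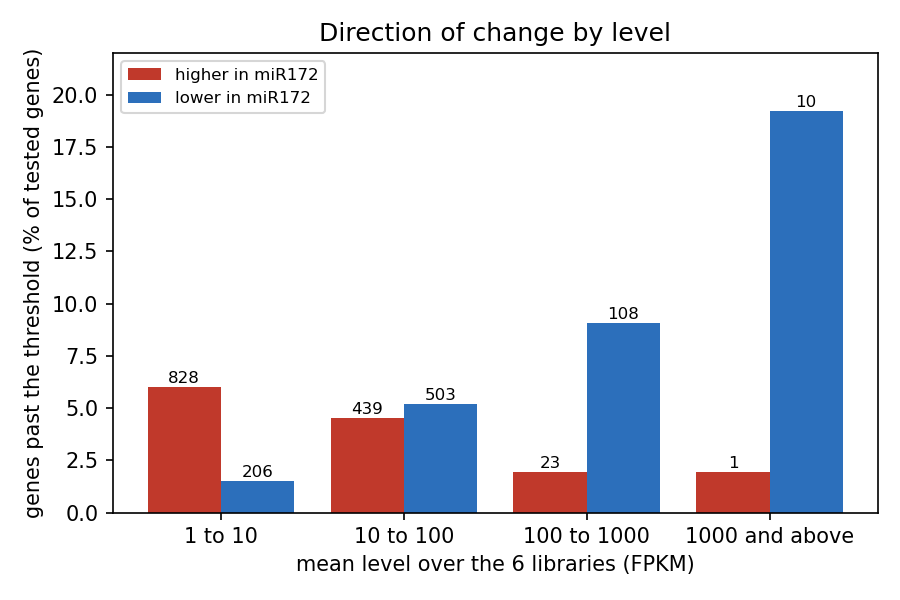
Genes past the threshold as a percentage of the genes tested (vertical axis) by mean level over the 6 libraries in FPKM (horizontal axis), with genes higher in miR172 fruit skin in red, genes lower in blue, and the number of genes above each bar. At 1 to 10 FPKM 828 genes rose and 206 fell, while at 1000 FPKM or more 1 rose and 10 fell.

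**Figure D3:**
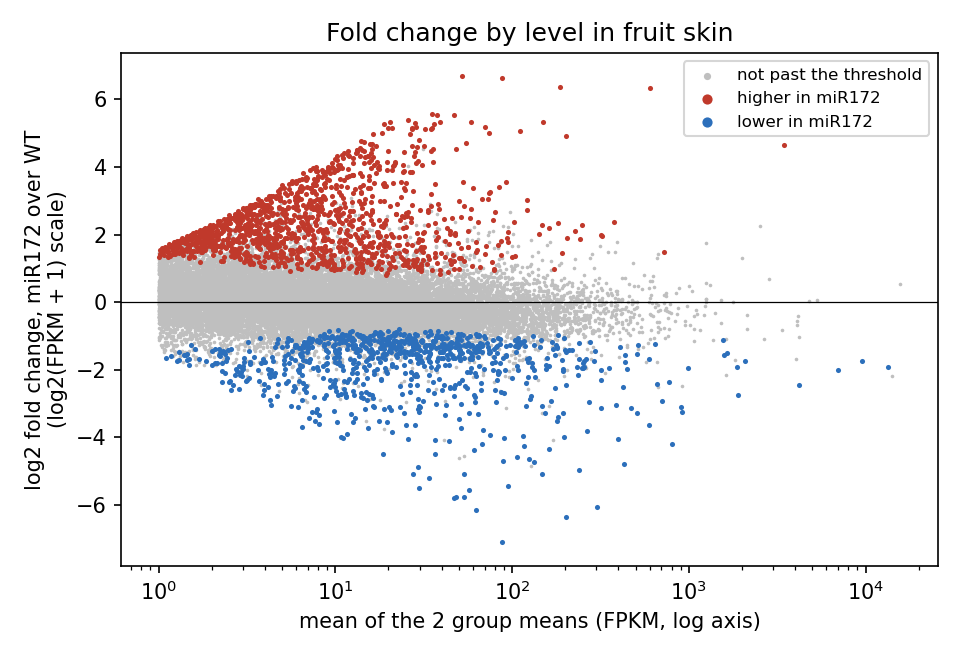
Log2 fold change of miR172 over WT fruit skin, on the log2(FPKM + 1) scale, against the mean of the 2 group means in FPKM (log axis), with 1 point per tested gene. The 1291 genes higher in miR172 skin (red) lie mostly at low levels, and the 827 genes lower (blue) reach to the highest levels.

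The most abundant transcripts held a smaller share of the reads in the miR172 libraries. The 10 most abundant genes of each library held 10.6, 10.4 and 10.3% of recovered reads in WT replicates 1, 2 and 3, and 5.12, 7.33 and 8.22% in miR172 replicates 1, 2 and 3. For the 100 most abundant genes the shares were 23.9, 25.3 and 24.3% in WT and 15.1, 19.0 and 21.6% in miR172 skin. Both ranges were apart, but 3 libraries against 3 cannot give an exact permutation p below 0.10. Of the 50 genes with the highest mean level, 34 had a lower mean in miR172 skin, of which 10 passed the threshold, and 1 gene passed as higher.

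Changed genes were found under every chromosome code. In the GDDH13 naming scheme the digits after MD give the chromosome, with 00 for unplaced sequence. The share of tested genes that changed ran from 7.42% for code 00 to 10.2% for code 01, and a difference between codes was not detected (permutation test with 10000 resamples, p = 0.62). Of 386 tested loci with no MD identifier, 31 rose and 14 fell, a share of 11.7% against 8.54% of the other tested genes (two-sided Fisher's exact test across genes, which are not independent replicates, p = 0.035). This difference depended on the processing. With no filter on level the loci changed less often, at 2.56% against 4.37% (the same exact test, p = 0.00034), and with voom on recovered reads the shares were 4.4% and 5.2% (exact p = 0.64). In the other alternatives, each tested in the same way, the share was higher among the loci, with exact p from 0.00045 to 0.43. A difference in direction between these loci and other changed genes was not detected (two-sided Fisher's exact test, p = 0.28). The count of 45 changed loci was 17 with voom, 21 with a filter of 5 FPKM, 22 without WT replicate 2, 18 without WT replicate 3, 21 without miR172 replicate 1 and 17 without miR172 replicate 2, settings under which fewer other genes were called as well.

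The first principal component of log2(FPKM + 1) held 53.2% of the variance and separated the genotypes, with WT libraries at -57.0, -90.8 and -64.9 and miR172 libraries at 82.0, 74.9 and 55.7. The next components held 20.3% and 18.1% and set miR172 replicate 3 apart from the others of its genotype. On the second, WT replicates 1, 2 and 3 lay at 71.2, -56.5 and -7.62. The median absolute log2 difference to libraries of the same genotype was 0.436, 0.423 and 0.217 in WT replicates 1, 2 and 3. It was 0.320, 0.267 and 0.445 in miR172 replicates 1, 2 and 3. The number of genes called was 2607 without WT replicate 1, 1145 without WT replicate 2 and 2622 without miR172 replicate 3. Spearman correlations across genes, which are not independent replicates, were 0.909 to 0.971 within genotypes and 0.879 to 0.929 between them. They were taken over all 48602 rows, including the 10798 at 0 in all libraries, whose shared ties can raise them. The chi-square per gene between replicates of a genotype was at least 30.6, so no pair looked like a library deposited more than once. Separately prepared libraries exceed counting noise in any case, and this says nothing on whether they are independent biological samples.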

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

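Scaling to recovered totals, voom on recovered reads, thinned reads and the shares by level were chosen after the data were seen. Against 2118 genes called, 1291 higher and 827 lower, voom on recovered reads gave 1268, with 631 higher. The filter of 5 FPKM gave 732 genes higher, with 15871 genes tested, no filter gave 534 lower, with 37804 genes tested, and scaling to recovered totals gave 471 lower, with a shift of the median. The cause was not tested further. Leaving out each library gave 816 to 2622 genes, 534 to 1531 higher and 248 to 1158 lower, with 1 library fewer in each fit. Among genes called in both, 0 had the opposite sign under any alternative. Since the genotypes did not overlap in these genes, leaving out a library or changing the filter or pseudocount could not reverse a sign. Of the named genes, MD10G1160400 lost its call with voom. Among changed genes of 1 to 10 FPKM, 80.1% rose, and 70.4 to 89.1% did under the alternatives. The lowest share came with the filter of 5 FPKM, which leaves only genes of 5 to 10 FPKM in this class. The lowest share under the other alternatives was 74.2%, without WT replicate 1. With the replicate number as a block 2308 genes were called. Deviations of same-numbered libraries correlated at 0.10, 0.101 and 0.039. Those of differently numbered libraries correlated at -0.152, -0.144, -0.046, -0.023, 0.021 and 0.103, the last for WT replicate 3 and miR172 replicate 2. The same-numbered values were all positive but small, and do not settle whether the numbers pair the samples. The block stayed an alternative because the labels do not say that the numbers pair them. Tests of gene lists, the flavonoid pathway, miR172 sites and the miR172 precursor, with their alternatives, were not run, for want of names and sequences. Thinning all libraries to the smallest total left 2113 genes called, 2068 of them among the 2118, but it removed at most 28.2% of a library's reads and says little of how depth limits the calls.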

Other observations

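All tests in this part of near-silent genes and of neighbours, and the count over other splits of the libraries, were chosen after the differences between genotypes had been seen, and the pattern by level was found in the same data that test it. Some genes were near-silent in WT skin and clearly expressed in all miR172 libraries. With at most 3 recovered reads over a genotype and at least 100 in each library of the other, 25 genes were near-silent in WT only and 0 in miR172 only. The other splits of the 6 libraries gave 0 genes in either direction. Those splits mix the genotypes, so a gene silent in a whole genotype and expressed in the other cannot count there. The counts belong to this single cutoff, and MD08G1062400, with 1, 8 and 0 recovered reads in the miR172 replicates, lay past it and was not counted. All miR172 libraries held more genes at 1 FPKM or more (23639 to 25536) than any WT library (22458 to 23305). Changed genes also lay close together in identifier order, which follows the chromosome in this naming scheme. Of pairs with adjacent identifiers, 116 changed in the same direction, 2.10 times the 55.3 obtained on average by permuting calls within chromosomes (permutation p = 0.001, the smallest that 1000 permutations can give), and 32 pairs changed in opposite directions. The longest run held 4 genes, and 5 runs of at least 3 genes held 16 genes.

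The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 2118 genes, 1 of the 10 splits (the real one) reached that number, and the highest of the others called 0 genes by limma, with 83 to 2363 genes at an unadjusted p under 0.05. The other splits mix the genotypes, so a difference between genotypes widens the spread within their groups. Calls were thus unlikely there in any case, and the 0 adds little.

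Abundant changed genes were mostly lower in miR172 skin. With values scaled to recovered totals, 66.41% of 131 such genes were still lower (95% interval 57.6 to 74.4%). This argues against the scaling between libraries as the whole cause, although the smaller share leaves room for scaling as part of the cause of that share. A scaling factor moves genes of all levels in the same direction. Of changed genes of 1 to 10 FPKM, 89.13% were higher after this scaling, against 80.08% as reported, so the contrast between levels remained. Library depth stays open: thinning reads to the smallest total gave 83.1% of 142 genes again, but it removed at most 28.2% of a library's reads and these calls lost 1 gene and gained 1, too little to test it. Gene length as the whole cause is argued against by splitting these genes into 3 groups by recovered length, where shares lower were 77.1%, 76.6% (62.0 to 87.7%) and 95.7% (85.5 to 99.5%) from the shortest to the longest, so length may still be part of the cause. An effect of the genotype, including a difference in ripeness or in the makeup of the sampled skin, stays open as untested, and the size of the pattern may rest partly on WT replicates 2 and 3, without which the share was 64.5% and 63.5%, the latter with an interval that reached equal numbers, while it was 89.9% of 238 genes (85.4 to 93.4%) without miR172 replicate 3.

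Neighbouring genes that changed alike may be copies that share reads, or genes whose transcripts overlap. Same-direction pairs 5 to 10 places apart were also more frequent than under permuted calls, at 1.267 times the permuted mean (373 pairs, 95% range of permuted calls 0.894 to 1.11 times). The excess was thus not limited to adjacent identifiers. This cannot show what lies behind the adjacent pairs, since the excess at each distance may have its own cause. Direction differed with expression level, and whether neighbours share a level was not tested. At 11 to 20 places the ratio was 1.03 (permutation p = 0.25). Reads shared by adjacent or overlapping genes, near-identical copies spread over longer arrays, and joint regulation of neighbouring genes all stay open, since no sequence was used here.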
